A study of Homo sapiens with 36 samples.

How the data were processed

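RNA from monocyte-derived macrophages of 6 human donors was sequenced in 36 libraries, 18 M0 and 18 M2. Per the labels' protocols, poly(A) RNA was selected with oligo(dT) beads, libraries were made with a directional kit, and paired reads were obtained on a NovaSeq instrument. Per the series' design text and the submitters' processing notes, reads were trimmed with Trimmomatic 0.39 after FastQC 0.12.1, aligned with STAR 2.7.10b to GRCh38.p14 with Ensembl release 113, marked for duplicates with Picard 3.0.0, assembled with StringTie 2.2.1 and counted per gene with HTSeq 2.0.3. Differential expression was computed by the authors with DESeq2 1.40.2. Whether counting used the strand, how duplicates and reads with several alignments were treated, and the model formula are not given in the sources used here. Values of antisense, overlapping and near-identical genes are therefore uncertain.

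The signal used as the main measure was the authors' deposited table of normalized counts of 58884 genes, which are gene counts divided by a size factor per library. Within a tolerance of 0.01, 100% of the values were whole multiples of a step in each library, so whole reads were recovered, with totals of 36.1 M to 70.8 M. These totals set the precision of low genes. M0 libraries held 47.3 ± 9.10 M reads and M2 libraries 43.1 ± 4.90 M (SD). The authors' deposited TPM table was used for levels and as an alternative scale, and which tool made it is not given in the sources used here. The fit in TPM had its own filter, a mean of at least 0.5 TPM, and a pseudocount of 0.1, and it tested 14931 genes. Members of a gene list tested in TPM can therefore differ from those tested in normalized counts. The authors' deposited tables of log2 fold changes, p-values and ratios (fold of mean TPM), and of gene ontology terms, were used only to compare or to describe. The table of ITIM genes holds separate blocks side by side, so each fold was read from its own block and checked against its own levels (55 folds). Of 602 ontology terms 4 had columns moved by commas in their names, and their p-values were not used. Gene coordinates are 1-based on GRCh38 and come from the GENCODE 44 annotation, not from the authors' release, and 58472 gene identifiers matched it.

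Libraries were assigned to donor, polarization and set from their titles. What the set letters stand for is not given in the sources used here. Libraries of a donor and polarization were averaged on the log2(normalized count + 1) scale, so that n is 6 donors. Genes with a mean of at least 10 were tested with limma 3.58.1 (R 4.3.3, eBayes with trend), with the donor as a fixed block and Benjamini-Hochberg adjustment over 14539 genes. A fold change is on the log2(value + 1) scale and understates changes of low genes. M0 and M2 cultures came from the same donors. In the check of this pairing, deviations from the group means correlated within each donor at 0.459 to 0.650, and at most at 0.130 with another donor. The closest libraries correlated at 0.789 after removal of group means, so none was a copy of another. Genes that can show the sex or genotype of a donor were left out everywhere (1173 genes).

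The design, the gene lists and all alternatives except those named in the closing section as chosen after seeing the data were fixed before the data were examined. The genes named are the 12 most raised and 12 most lowered with a mean of at least 100 normalized counts and the same direction in 6 of 6 donors, up to 4 members per list by absolute log2 fold change past the threshold, taken by rank, and 25 fixed genes. Some genes that meet this rule are not reported here. Exceptions are named as such. Gene lists were tested with camera at a preset correlation of 0.01 and at an estimated correlation, and with fry. For each list, the signs of the donors' differences were also flipped in all 32 ways and the absolute mean relative to all genes compared, a test chosen after the lists' results were seen. Alternatives covered the donor block, the unit of replication, pseudocounts of 0.1 and 10, filters of 0 and 100, TPM, centring, quantile normalization, eBayes settings, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads (6123 and 6850 genes called), sets and leaving out each donor.

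The fit was tested on simulated counts of 15329 genes for the comparison of M2 with M0. Of genes changed 1.5-fold, 60% were called by limma, of those changed 2-fold 94%, 4-fold 96% and 8-fold 100%, and 4.89% of calls were among unchanged genes. Only a small share of genes was changed, all with a mean of at least 100 counts. Genes varied independently, and no difference between sets was built into this comparison. These shares therefore need not hold for lower genes or where many genes change. Reads are not independent molecules without molecular identifiers. Standard errors from limma cover the spread between donors, and bootstrap intervals of a list's median cover the spread between its members, not between donors.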

Results

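Gene expression was measured by poly(A) RNA sequencing in human macrophages grown from blood monocytes of 6 donors. After 7 days of culture the cells were kept for a further week either without additions (M0) or with the cytokines TGF-beta and IL-10 at 50 ng/mL (M2), a treatment used to obtain macrophages with anti-inflammatory and tissue-repair features. Each donor gave 3 libraries per polarization, so that 18 M0 and 18 M2 libraries were compared, with the donor as the unit of replication (n = 6). By the letters in their titles the libraries fell into sets A and B of all donors, set C of donors 4 to 6, and a set without a letter, called unsuffixed here, of donors 1 to 3, which carried its own library-name prefix. What the letters stand for, such as a culture, a well, an RNA sample or a library, is not given in the sources used here, so values per set compare sets of libraries and not necessarily separate cultures. Reads assigned to genes ranged from 36.1 M to 70.8 M per library, with a median of 43.0 M. The labels describe 2 culture media without saying which libraries were grown in which.

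Polarization and donor were the main sources of variation. The M0 and M2 libraries were separated completely on the first principal component, which held 30.3% of the variance, and the nearest library of each of the 36 libraries had the same polarization. Polarization alone accounted for 28.9% of the total sum of squares, donor for 30.2% and set for 10.2%. The second component (12.8%) set the M0 libraries of sets A and B of donors 1 to 3 apart from the other M0 libraries.

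**Figure D1:**
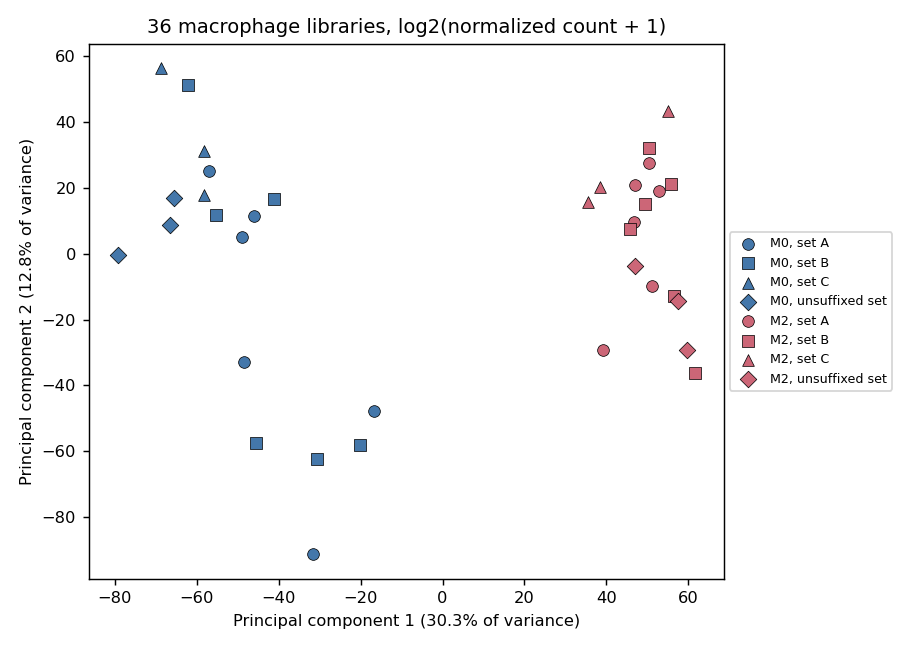
Principal components 1 (x axis) and 2 (y axis) of the log2 normalized counts of 36 libraries, each point a library, colored by polarization and shaped by set. M0 and M2 libraries do not overlap on component 1, which holds 30.3% of the variance, and on component 2, which holds 12.8%, 6 M0 libraries of sets A and B lie below the other M0 libraries, in a range that some M2 libraries of donor 2 share or come near.

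The comparison of M2 with M0 asks which genes differ after exposure to TGF-beta and IL-10. M2 cells held far more transcripts of MMP7, FN1 and CCL18, and far fewer of FCN1, SERPINB2 and THBS1. MMP7, a matrix metalloproteinase, went from 249 ± 138 to 35997 ± 25411 normalized counts (mean ± SD, n = 6 donors), and FN1, which encodes fibronectin, from 1112 ± 1005 to 46893 ± 24319. CCL18, a chemokine made by alternatively activated macrophages, went from 459 ± 292 to 28714 ± 14367. Of 14539 genes tested with limma, 3207 were higher and 3002 lower in M2 at an adjusted p under 0.05, and 8330 were not called. Which direction held more genes depended on the scaling, with 2448 higher and 3097 lower in TPM, 2993 and 3381 after centring on the median, and 2823 and 3890 after quantile normalization. With a log2 fold change of at least 1 as well, 1096 genes were higher and 554 lower.

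The numbers of genes called were lower within single sets. Set A alone gave 2190 higher and 1667 lower, set B alone 2368 and 1816, set C alone (donors 4 to 6) 981 and 699, and the unsuffixed set alone (donors 1 to 3) 1769 and 1483. In donors 4 to 6 only, 2376 genes were higher and 1997 lower. With no donor block 2321 genes were higher and 2053 lower, and 20 of 147 named genes lost their call (limma adjusted p from 0.0521 to 0.360). These were SIRPA, LILRB2, TREM2, CD274, IFI27, IFI44L, HLA-DPB1, FCRL5, FABP4, SLC2A5, RRM2, CDK1, ASNS, MS4A1, PPBP, CAMP, MYL9, PDCD1, FCRL1 and CD33. Without sets A and B of donors 1 and 2, whose M0 libraries held red-cell transcripts, 2680 genes were higher and 2512 lower.

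The largest increase among abundant genes was that of CYP24A1, the vitamin D 24-hydroxylase (ENSG00000019186, GRCh38 chromosome 20, 54153446 to 54173986), with a log2 fold change of 7.54 ± 0.46 (SE; limma adjusted p = 1.74e-05). Its M0 level was 0.798 ± 1.80 normalized counts, so the size of this fold depends on the pseudocount of 1. MMP7 (ENSG00000137673, chromosome 11, 102520508 to 102530750) rose by 7.22 ± 0.36 and CEMIP, a hyaluronan-binding protein, by 6.89 ± 0.46. The other genes among the 12 most raised were FCRLA (6.62 ± 0.71), IL17RB (6.35 ± 0.33), the long non-coding RNA CASC15 (6.23 ± 0.38), CCL18 (6.21 ± 0.34; ENSG00000275385, chromosome 17, 36064280 to 36072032), LGI2 (6.12 ± 0.26), the somatostatin receptor SSTR2 (6.11 ± 0.36), DACT1 (5.83 ± 0.30), FN1 (5.81 ± 0.19; ENSG00000115414, chromosome 2, 215360440 to 215436073) and the metallothionein MT1H (5.77 ± 0.46). All were higher in 6 of 6 donors.

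The 12 most lowered genes were lower in 6 of 6 donors. PID1 (ENSG00000153823, chromosome 2, 228850526 to 229271285) had a log2 fold change of -6.67 ± 0.51 and SERPINB2, plasminogen activator inhibitor 2 (ENSG00000197632, chromosome 18, 63871692 to 63903888), of -6.64 ± 0.76. THBS1, thrombospondin 1, fell by 6.06 ± 0.31, FCER2, the low-affinity IgE receptor, by 6.05 ± 0.37, and FCN1, ficolin 1, had a log2 fold change of -5.39 ± 0.32. APOBEC3A (-5.30 ± 0.24), CCL24 (-5.17 ± 0.66), IL3RA (-4.97 ± 0.26), COLEC12 (-4.86 ± 0.29), MEFV (-4.27 ± 0.25), LEP (-3.83 ± 0.33) and IL18BP (-3.61 ± 0.36) followed.

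**Figure D2:**
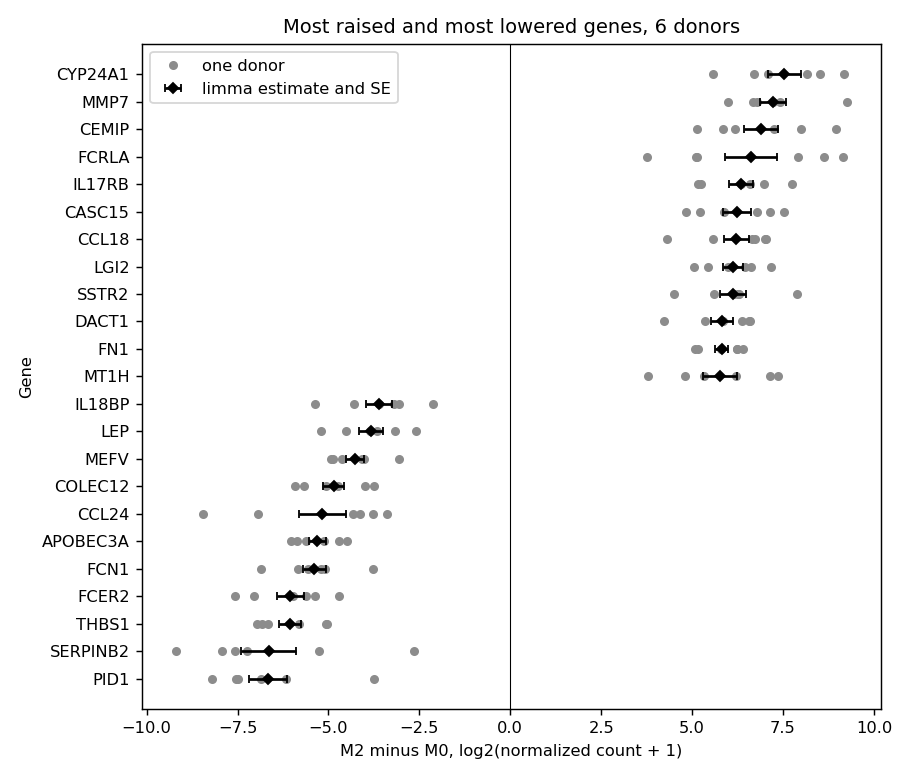
M2 minus M0 difference (x axis, log2 of normalized count + 1) of the most raised and most lowered genes (y axis), with 6 donors as grey points and the limma estimate and its standard error as black diamonds. IL3RA is not drawn. All donors lie on the same side of 0 for each gene, from -6.67 for PID1 to 7.54 for CYP24A1 in the mean.

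A total of 35 gene lists were fixed before the data were examined. With camera at a preset correlation of 0.01, 16 of the 35 lists differed from the other genes at an adjusted p under 0.05, 12 upward and 4 downward. With a correlation estimated from the data camera called 0 lists, with a smallest adjusted p of 0.187 and 5 lists at an unadjusted p under 0.05, and fry, which does not compare a list with other genes, called 19. Within the unsuffixed set alone 10 lists were called. With no donor block 5 of the 16 lost their call, the alternative-activation (adjusted p = 0.0882), inflammatory (0.220), complement (0.105), proliferation (0.0874) and dendritic cell lists (0.0882).

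Among the targets of each added cytokine more members rose than fell. Of 32 TGF-beta/SMAD targets tested, 21 rose and 4 fell (24 and 4 adjusted over the list alone). The largest change was a fall, that of THBS1 (-6.06 ± 0.31), followed by rises of ID1 (4.75 ± 0.46), the inhibitory SMAD gene SMAD6 (4.50 ± 0.32) and ID3 (4.34 ± 0.19). PMEPA1 rose by 3.02 ± 0.10, SMAD7 by 2.23 ± 0.09 and TGFBI by 1.76 ± 0.19. The camera adjusted p was 1.51e-07 with the preset correlation, and the adjusted p was 0.187 with an estimated correlation. Of 29 IL-10/STAT3 targets, 20 rose and 3 fell (20 and 3 adjusted over the list alone), with CCL18, PDPN (4.49 ± 0.28), the haemoglobin scavenger receptor CD163 (3.46 ± 0.22; ENSG00000177575, chromosome 12, 7470813 to 7503893), coagulation factor F5 (3.25 ± 0.31) and SOCS3 (3.24 ± 0.24) among them. CD163 reached 273651 ± 40398 normalized counts in M2 against 29101 ± 14858 in M0 (n = 6). The adjusted p of this list was 3.00e-06, and it was 0.187 with an estimated correlation. IL10 itself had a log2 fold change of 0.57 ± 0.28 that did not pass (limma adjusted p = 0.132).

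In the matrix, adhesion and phagocytic receptor lists more members rose than fell. Of 37 matrix and matrix-remodelling genes, 24 rose and 3 fell (24 and 3 adjusted over the list alone), led by MMP7, THBS1 (lower), FN1 and the macrophage elastase MMP12 (5.48 ± 0.21), and SPP1, osteopontin, rose by 2.78 ± 0.19 (adjusted p = 3.00e-06 for the list, and adjusted p = 0.187 with an estimated correlation). Among 29 integrins and adhesion genes, 19 rose and 4 fell (20 and 4 adjusted over the list alone). The integrin subunits ITGAV (2.32 ± 0.09) and ITGB3 (2.05 ± 0.09) were higher, while CDH1, E-cadherin, fell by 3.41 ± 0.58 and ICAM3 by 2.26 ± 0.32 (adjusted p = 0.00101, and adjusted p = 0.492 with an estimated correlation). Of 26 efferocytosis and phagocytic receptor genes, 13 rose and 1 fell (15 and 2 adjusted over the list alone), including PROS1, protein S (3.23 ± 0.20), and the receptor kinase MERTK (1.60 ± 0.23), which binds it (adjusted p = 0.00262, and adjusted p = 0.187 with an estimated correlation).

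Of 20 microglia-type TGF-beta dependent genes, 13 rose and 1 fell (13 and 1 adjusted over the list alone), with OLFML3 (4.54 ± 0.29), PROS1, CRYBB1 (2.43 ± 0.38) and SLC2A5 (1.70 ± 0.44) leading and CSF1R higher by 1.07 ± 0.15. CX3CR1 did not pass (0.52 ± 0.46, limma adjusted p = 0.389). The list had an adjusted p of 0.00289, and an adjusted p of 0.492 with an estimated correlation. The number that rose was 7 with no donor block, 7 without sets A and B of donors 1 to 3, and 6 in donors 4 to 6 only. Of 20 complement genes, 10 rose and 2 fell (10 and 2 adjusted over the list alone). CFP, properdin, fell by 4.05 ± 0.34, C1S rose by 2.84 ± 0.38 and the complement receptor VSIG4 by 2.29 ± 0.28 (adjusted p = 0.0451, and adjusted p = 0.595 with an estimated correlation). Without donor 1, 4 or 6 the list's adjusted p was 0.0671, 0.0559 and 0.0638, in the unsuffixed set alone 0.710 with the direction turned, and without sets A and B of donors 1 to 3, where 3 members rose, 0.499.

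Alternative-activation genes split. Of 27 tested, 12 rose and 5 fell (16 and 6 adjusted over the list alone). CCL18, FN1 and the scavenger receptor MARCO (4.44 ± 0.36) rose, as did MRC1, the mannose receptor (0.86 ± 0.21), and TREM2 (0.71 ± 0.20). CCL24, CLEC10A (-3.33 ± 0.30), CD200R1 (-3.08 ± 0.53) and CD209 (-1.74 ± 0.20) fell, and of 15 dendritic cell markers 7 fell and 2 rose. The list's adjusted p was 0.0451, and the adjusted p was 0.532 with an estimated correlation. Without donor 1, 3 or 6 the list's adjusted p was 0.0515, 0.0504 and 0.0685, in donors 4 to 6 only 0.0624, in the unsuffixed set alone 0.662, and without sets A and B of donors 1 to 3 it was 0.353. TREM2 lost its call without donor 1 or 2 (limma adjusted p = 0.0520 and 0.0581) and had a log2 fold change of -0.40 in the unsuffixed set alone.

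Inflammatory genes also went both ways. Of 27 M1-type markers, 10 fell and 6 rose (10 and 6 adjusted over the list alone). The lymph-node homing receptor CCR7 fell by 3.41 ± 0.45, the neutrophil chemokine CXCL8 by 3.25 ± 0.11, IDO1 by 3.08 ± 0.39 and TNF by 0.99 ± 0.12, whereas INHBA (2.56 ± 0.82) and IL1B (1.60 ± 0.28) rose (adjusted p = 0.0466 downward, and adjusted p = 0.587 with an estimated correlation). Without donor 1, 2 or 3 the list's adjusted p was 0.0981, 0.0576 and 0.0916, in TPM 0.0976 and after centring on the median 0.0782. It was 0.381 in donors 4 to 6 only, 0.707 in set C alone, 0.710 in the unsuffixed set alone and 0.360 without sets A and B of donors 1 and 2. INHBA lost its call without donor 2, 3, 4, 5 or 6 (limma adjusted p from 0.0600 to 0.0975), and CCR7 had a log2 fold change of 0.10 in set C alone. Of 22 chemokines, 5 rose and 5 fell (5 and 5 adjusted over the list alone; adjusted p = 0.493), with CCL23 higher by 4.30 ± 0.40. Of 22 chemoattractant receptors, 8 rose and 5 fell (9 and 5 adjusted over the list alone, and 5 rose with no donor block; adjusted p = 0.573), among them the formyl peptide receptors FPR1 (2.69 ± 0.29) and FPR2 (2.42 ± 0.36) and the monocyte chemokine receptor CCR2 (2.54 ± 0.41).

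Among interferon-stimulated genes more members fell than rose. Of 37 tested, 28 fell and 0 rose by limma (29 and 1 adjusted over the list alone, 30 and 1 at an unadjusted p under 0.05, and 30 and 0 by edgeR). With no donor block 14 fell, and without the unsuffixed set 18. IFI27 fell by 3.02 ± 0.40, ISG20 by 2.45 ± 0.22, the sialic acid receptor SIGLEC1 by 2.24 ± 0.50 and IFI44L by 1.92 ± 0.43. The adjusted p was 1.51e-07, and the adjusted p was 0.587 with an estimated correlation, at an estimated correlation of 0.608 between members. Of 16 MHC class II presentation genes, 7 rose and 1 fell (7 and 2 adjusted over the list alone; adjusted p = 0.107), with HLA-DOA (3.20 ± 0.32), the class II transactivator CIITA (1.11 ± 0.14) and HLA-DRA (0.78 ± 0.14) higher. The list was called upward in TPM (adjusted p = 0.0365), without donor 2 (0.0267), without donor 5 (0.0352), without the unsuffixed set (0.0173) and in set A (0.00104) or B (0.0295) alone, all at the preset correlation (over all libraries adjusted p = 0.826 with an estimated correlation), whereas 2 members rose without sets A and B of donors 1 to 3. HLA-DRA had a log2 fold change of -0.0033 in the unsuffixed set alone. Of 17 MHC class I genes, 3 rose and 5 fell (3 and 5 adjusted over the list alone, 1 and 1 with no donor block, 1 and 2 in donors 4 to 6 only; adjusted p = 0.493), with PSMB9 lower by -0.64 ± 0.08 and NLRC5 higher by 0.44 ± 0.06.

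**Figure D3:**
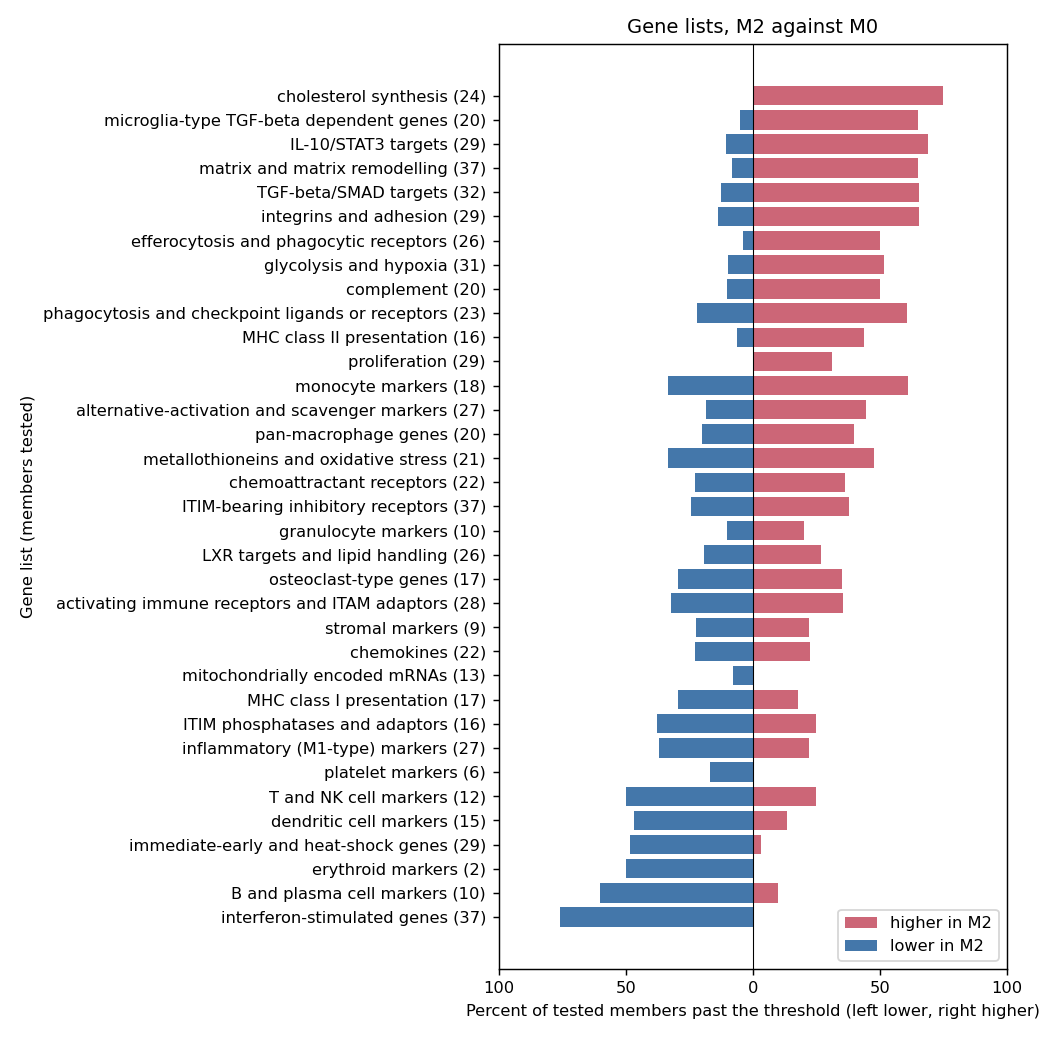
Percent of tested members of each of 35 gene lists (y axis, with the number of members tested) that were higher (right, red) or lower (left, blue) in M2 at an adjusted p under 0.05 (x axis). Cholesterol synthesis has 18 of 24 members higher and 0 lower, and interferon-stimulated genes have 28 of 37 lower and 0 higher.

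Receptors with an immunoreceptor tyrosine-based inhibitory motif (ITIM), which dampen immune cell signalling, were the subject of the authors' own tables. The list tested here was fixed beforehand and is not the authors' list. Of its 37 tested members, 14 rose and 9 fell (15 and 9 adjusted over the list alone), 23 in all against 15 with no donor block and 10 in set C alone. The list was not called in normalized counts (camera adjusted p = 0.171, and 0.769 with an estimated correlation). At the preset correlation camera called it upward in set A alone (adjusted p = 0.0194) and in TPM (0.00154), where the filter of 0.5 TPM can leave other members. By edgeR 12 rose and 11 fell. The median was 0.32 over all libraries, -0.037 without sets A and B of donors 1 and 2, and -0.085 without those of donors 1 to 3. SIGLEC10, a sialic acid receptor that binds CD24 (ENSG00000142512, chromosome 19, 51410020 to 51417803), rose most, by 4.43 ± 0.15 (limma adjusted p = 2.40e-06), from 16.0 ± 11.0 to 272 ± 49.8 TPM (SD, n = 6). CD72 rose by 3.08 ± 0.32, FCGR2B, the inhibitory IgG receptor, by 2.31 ± 0.26, SIT1 by 2.28 ± 0.23 and the collagen receptor LAIR1 by 1.32 ± 0.10, the last from 213 ± 30.6 to 465 ± 88.2 TPM. LILRB1 rose by 1.13 ± 0.18, CD300A by 1.10 ± 0.24 and LILRB2 by 0.87 ± 0.30. LILRB2 lost its call without donor 2, 4 or 6 (limma adjusted p = 0.111, 0.0574 and 0.0994).

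The abundant receptors LILRB4 (781 ± 176 TPM in M0 and 783 ± 133 in M2), LILRB3, PECAM1 and SIGLEC7 did not pass (LILRB3 passed in the unsuffixed set alone, at -0.51), and SIRPA, the CD47 receptor, fell by 0.24 ± 0.05. CD22 fell by 1.93 ± 0.17, from 47.5 ± 10.1 to 9.31 ± 2.44 TPM, and PILRA fell by 0.50 ± 0.08. In donors 1 to 3 the log2 fold change of CD22 was -4.38 in the unsuffixed set and -0.38 in sets A and B (limma adjusted p of the difference 0.0745). CD33 was lower by -0.15 ± 0.05 and lost its call without donor 3, 4, 5 or 6 (limma adjusted p = 0.118, 0.139, 0.0920 and 0.110). The lymphocyte-associated FCRL3 (-2.75 ± 0.64), FCRL5 (-2.65 ± 0.64), CD5 (-2.64 ± 0.43), PDCD1 (-2.20 ± 0.54) and FCRL1 (-1.63 ± 0.50; lost without donor 1, 2, 3 or 6, limma adjusted p = 0.0806, 0.0746, 0.0848 and 0.0541) fell from low levels, and the B-cell transcript MS4A1 fell with them, from 227 ± 248 to 17 ± 25 normalized counts. FCRL5 had a log2 fold change of 0.079 in set C alone. Reads of FCGR2B and FCGR2C, of FCGR3A and FCGR3B and within the LILR and SIGLEC families may be shared between near-identical genes, and these values are uncertain to that extent.

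**Figure D4:**
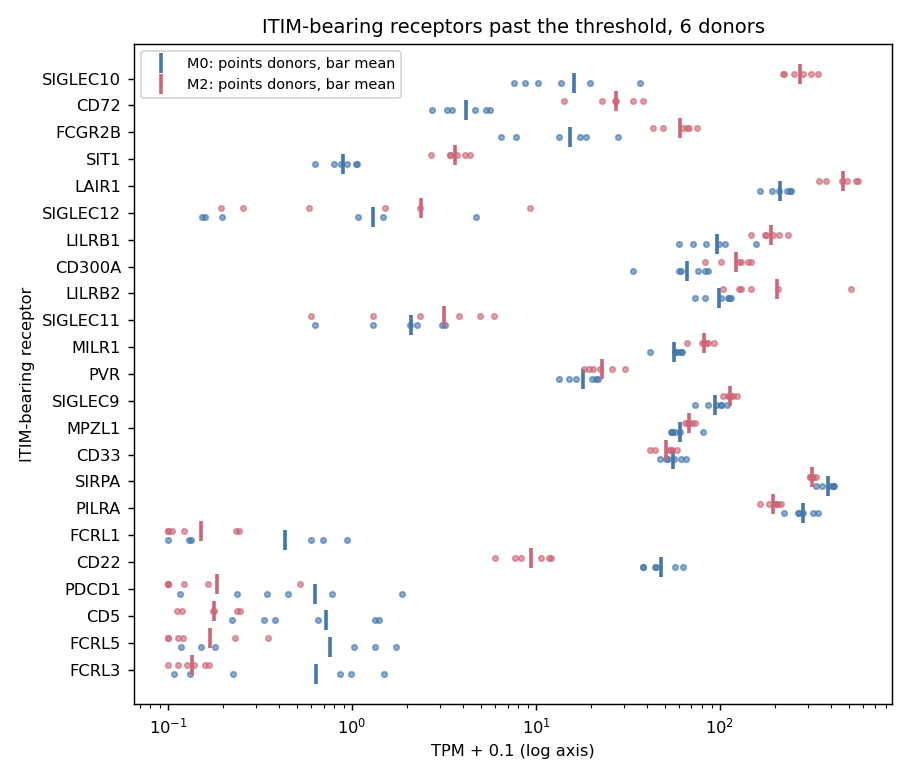
TPM + 0.1 (x axis, log scale) of the ITIM-bearing receptors past the threshold (y axis) in M0 (blue) and M2 (red), with points for 6 donors and bars for means. SIGLEC10 has means of 16.0 TPM in M0 and 272 TPM in M2, and CD22 has means of 47.5 and 9.31 TPM.

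Of 16 ITIM phosphatases and adaptors, 4 rose and 6 fell (4 and 6 adjusted over the list alone; adjusted p = 0.512). DOK2 fell by 2.14 ± 0.20 and the kinases FYN by 1.28 ± 0.17 and SRC by 0.70 ± 0.06, and GRB2 rose by 0.58 ± 0.08. Of 28 activating immune receptors and ITAM adaptors, 10 rose and 9 fell (10 and 9 adjusted over the list alone, 6 and 5 with no donor block; adjusted p = 0.949), with a median log2 fold change of -0.13 and a mean of 0.16. FCGR3A, CD16a, rose by 3.20 ± 0.19 and CD300E by 3.01 ± 0.25, and CLEC4E fell by 2.52 ± 0.15. Of 23 phagocytosis and checkpoint genes, 14 rose and 5 fell (14 and 6 adjusted over the list alone; adjusted p = 0.0326, and adjusted p = 0.492 with an estimated correlation). SIGLEC10, NT5E (2.62 ± 0.39), which makes adenosine, and CD274, the PD-1 ligand (0.68 ± 0.14), were higher. The list's adjusted p was 0.0705 in the unsuffixed set alone and 0.0544 without sets A and B of donors 1 and 2.

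Most cholesterol synthesis genes rose by small amounts. Of 24 tested, 18 rose and 0 fell by limma (19 and 0 adjusted over the list alone, 20 and 0 at an unadjusted p under 0.05, and 16 and 0 by edgeR), with DHCR7 (0.85 ± 0.13), SQLE (0.81 ± 0.07) and TM7SF2 (0.69 ± 0.09) among them (adjusted p = 3.00e-06, and adjusted p = 0.532 with an estimated correlation). In the unsuffixed set alone the adjusted p was 0.116, and without sets A and B of donors 1 to 3 10 members rose. Of 26 LXR targets and lipid handling genes, 7 rose and 5 fell (8 and 6 adjusted over the list alone, 3 and 9 without sets A and B of donors 1 to 3; adjusted p = 0.846), with a median of 0.040 and a mean of -0.018. The cholesterol exporter ABCG1 fell by 3.48 ± 0.36 and FABP4 by 2.49 ± 0.32, and PLTP rose by 2.76 ± 0.33 and APOE by 1.42 ± 0.20. Of 31 glycolysis and hypoxia genes, 16 rose and 3 fell (16 and 3 adjusted over the list alone), led by CA12 (4.55 ± 0.30), EGLN3 (2.73 ± 0.51) and PFKFB3 (1.71 ± 0.18; adjusted p = 0.00289 for the list, and adjusted p = 0.532 with an estimated correlation).

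Of 21 metallothionein and oxidative stress genes, 10 rose and 7 fell (10 and 8 adjusted over the list alone; adjusted p = 0.493), and the median of -0.15 and the mean of 0.91 differed in sign. The metal-binding MT1H, MT1G (5.21 ± 0.58) and MT1M (4.41 ± 0.58) rose. Of 29 immediate-early and heat-shock genes, 1 rose and 14 fell (1 and 14 adjusted over the list alone), with EGR3 (-2.11 ± 0.41), ASNS (-1.86 ± 0.37), KLF4 (-1.84 ± 0.20) and NR4A1 (-1.75 ± 0.30) lowest (adjusted p = 0.00215, and adjusted p = 0.187 with an estimated correlation). In the unsuffixed set alone the adjusted p was 0.636. Of 29 proliferation genes, 9 rose and 0 fell by limma (9 and 0 adjusted over the list alone, 15 and 0 at an unadjusted p under 0.05, and 8 and 0 by edgeR), with RRM2 (1.08 ± 0.28) and CDK1 (0.99 ± 0.27) highest (adjusted p = 0.00558, and adjusted p = 0.812 with an estimated correlation). The number that rose was 0 without the unsuffixed set (limma; list median 0.11, adjusted p = 0.856), 2 with no donor block, 2 in donors 4 to 6 only (adjusted p = 0.381), and 17 without sets A and B of donors 1 to 3 (list median 1.21). In set A alone the list's direction was downward (adjusted p = 0.0519), in sets B and C alone the adjusted p was 0.101 and 0.606, and without donor 2 it was 0.0719. With the donors' signs flipped, 8 of 32 flips gave a list mean as large. CDK1 lost its call without donor 1 (limma adjusted p = 0.0510) and had a log2 fold change of -0.023 in set C alone. Of 13 mitochondrially encoded mRNAs, 0 rose and 1 fell by limma (0 and 1 adjusted over the list alone, 1 and 1 at an unadjusted p under 0.05, and 1 and 1 by edgeR; adjusted p = 0.493). That gene, MT-ND6, lies antisense to other mitochondrial transcripts and had log2 fold changes of -1.21 ± 0.18 in normalized counts and 0.14 in TPM.

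Cell-type markers were examined in the same way. Of 20 pan-macrophage genes, 8 rose and 4 fell (8 and 4 adjusted over the list alone, 4 rose without sets A and B of donors 1 to 3; adjusted p = 0.660), with the cathepsin CTSL (1.74 ± 0.13) and CD14 (1.21 ± 0.25) higher and LGALS3 lower (-1.59 ± 0.09). Of 18 monocyte markers, 11 rose and 6 fell (11 and 6 adjusted over the list alone; adjusted p = 0.493). Their median was 0.80, their mean -0.35, and camera and fry gave opposite directions. S100A8 (3.20 ± 0.35) and FPR1 rose, while SERPINB2, THBS1 and FCN1 fell. Of 15 dendritic cell markers, 2 rose and 7 fell (2 and 7 adjusted over the list alone; adjusted p = 0.0451, and adjusted p = 0.492 with an estimated correlation), with CADM1 higher (4.02 ± 0.26) and IRF4 lower (-3.69 ± 0.27), and without donor 1 or 4 the list's adjusted p was 0.0671 and 0.0650. It was 0.131 in TPM, 0.0746 after centring on the median, 0.174 in set C alone, 0.165 in the unsuffixed set alone and 0.104 without sets A and B of donors 1 to 3. Of 17 osteoclast-type genes, 6 rose and 5 fell (6 and 5 adjusted over the list alone, 3 rose with no donor block; adjusted p = 0.828), with SPP1 and ITGB3 higher and ACP5 lower (-1.27 ± 0.09).

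Markers of other cell types that the cultures could hold went in both directions. Of 12 T and NK cell markers, 3 rose and 6 fell (4 and 7 adjusted over the list alone, 2 fell in donors 4 to 6 only, camera adjusted p = 0.430), with a median of -1.11 in normalized counts. NKG7 was higher (4.42 ± 0.56) and GNLY (-3.29 ± 0.64) and PRF1 (-3.27 ± 0.52) lower. In TPM the median was 1.06, but over the members that passed the filter of 0.5 TPM. These can be other genes, so the medians do not show that the same markers change sign with the unit. Of 10 B and plasma cell markers, 1 rose, FCRLA, and 6 fell (1 and 6 adjusted over the list alone; adjusted p = 0.155), including MS4A1 (-3.33 ± 0.59) and CD79B (-2.41 ± 0.38). With no donor block 1 fell, as in donors 4 to 6 only. At the preset correlation camera called the list downward without donor 5 (adjusted p = 0.0410), in set A alone (0.0494) and in the unsuffixed set alone (0.0412). Over all libraries the adjusted p was 0.826 with an estimated correlation, which was 0.818 between members. Of 6 platelet markers 1 fell, PPBP (-1.31 ± 0.45), and 0 rose by limma (0 and 0 adjusted over the list alone, 3 lower and 0 higher at an unadjusted p under 0.05, 2 and 0 by edgeR; adjusted p = 0.343). PPBP lost its call without donor 1, 3, 4, 5 or 6 (limma adjusted p from 0.0585 to 0.120) and had a log2 fold change of 2.95 in the unsuffixed set alone and 0.40 without sets A and B of donors 1 and 2. Of 2 erythroid markers tested, HBB fell by 3.21 ± 0.92 and 0 rose by limma (0 and 1 adjusted over the list alone, 0 higher and 1 lower at an unadjusted p under 0.05, 0 and 2 by edgeR; adjusted p = 0.343). HBB lost its call without donor 1 or 2 (limma adjusted p = 0.0545 and 0.0614), and in the M0 libraries of sets A and B of these donors it stood at 513 to 2189 normalized counts against at most 86.7 in the other 14 M0 libraries. Of 10 granulocyte markers, 2 rose and 1 fell (2 and 1 adjusted over the list alone; adjusted p = 0.921), with FCGR3B higher by 3.28 ± 0.37 and CAMP by 1.28 ± 0.30, the latter at -1.19 in the unsuffixed set alone, and camera and fry gave opposite directions. Of 9 stromal markers, 2 rose and 2 fell (2 and 2 adjusted over the list alone; adjusted p = 0.673), with PDGFRA higher by 4.03 ± 0.20 and MYL9 by 0.91 ± 0.24.

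The M2 minus M0 difference was also compared between parts of the design. Between sets A and B of the 6 donors it differed for 0 genes by limma (769 at an unadjusted p under 0.05, with 727 expected by chance) and for 0 by edgeR (856 unadjusted). Of simulated genes given a log2 difference of 2 between these sets, 79% were called by limma, so smaller differences could be missed. Between donors 1 to 3 and donors 4 to 6, in sets A and B, the M2 minus M0 difference differed for 0 genes by limma, with 1631 at an unadjusted p under 0.05. Between the unsuffixed set and the mean of sets A and B of donors 1 to 3 it differed for 0 genes by limma (3660 unadjusted, smallest adjusted p = 0.0504), whereas edgeR called 651 genes higher and 605 lower (4195 unadjusted). FSCN1, NDRG1, KLHL24, CSF3R and DDIT4L, singled out after their values were seen, were past the threshold in both the comparison of all libraries and the unsuffixed set alone with opposite signs. CSF3R had log2 fold changes of 0.83 and -0.78.

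The authors' deposited table of differential genes, made with DESeq2, listed 1567 genes as higher and 1492 as lower in M2, of which 1400 and 1202 had an adjusted p under 0.05. Of the listed genes 1642 passed the filter on low counts used here. Of these 1639 had the same sign here and 1531 were also past the threshold, with 0 past it in the opposite direction. The authors' deposited table of ITIM genes gave SIGLEC10 a fold of 17.0 and CD22 a fold of 0.196 between mean TPM. Of its 47 genes, which differ from the ITIM list fixed here, 42 were tested. Among these 22 rose, 9 fell and 11 did not pass. The authors' deposited list of prioritized genes held 38 that were tested here, of which 21 rose and 6 fell. In the authors' deposited table of 602 gene ontology terms the smallest adjusted p was that of collagen-containing extracellular matrix (67 genes, adjusted p = 2.08e-13), followed by extracellular matrix organization (62 genes) and extracellular structure organization (67 genes), both with an adjusted p of 5.12e-11. The authors' differential genes and folds were computed on the same libraries and are not independent evidence of direction, and how the prioritized genes were chosen is not given in the sources used here.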

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

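The tests of explanations for CD22 and its companions, of red-cell transcripts and of a batch or medium, and the splits of all genes, of sets A and B against each other, of donors 1 to 3 against 4 to 6 of the unsuffixed set against A and B, and of single gene lists, were chosen only after the result was seen. The thinning test and the remaining splits were set up before.

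CD22 was lower in M2 in 6 of 6 donors, and the tables argue against B cells as the cause: in donors 4 to 6, whose M0 libraries held a mean of 16.7 MS4A1 counts against 436 in donors 1 to 3, the smallest CD22 difference was still -1.70 (log2). Scaling does not account for it either, with -1.95 in the less changed of TPM and median-centred values. The M0 level of CD22 differed between sets, however, with means of 5261 counts in the unsuffixed set and 637 in sets A and B of the same donors, and since the labels do not say how the sets differ, the share of the cytokines in the change stays open. For FCRL1, FCRL3, FCRL5 and CD5 the M0 levels were a median of 24.2 times higher in donors 1 to 3 than in donors 4 to 6, against 26.2 times for MS4A1. The ratio was 20.1 to 31.1 for the FCRL genes, so B cells in the M0 cultures of donors 1 to 3 are a candidate explanation for these. CD5 had a lower ratio of 9.29. In donors 1 to 3 it stood at 9.54 counts in the unsuffixed M0 libraries and 78.6 in sets A and B, against 297 and 506 for MS4A1, so it followed MS4A1 less closely. Between the same libraries FCRL5 went with MS4A1 (74.3 and 141). FCRL1 (52.4 and 29.4) and FCRL3 (94.5 and 83.0) went the opposite way, which limits the explanation for these genes. PDCD1 had a ratio of 0.444, but this rested on donor 5, at 1.76 TPM in M0. Donors 4 and 6 stood at 0.138 and 0.0160 TPM, below the 0.245 to 0.674 TPM of donors 1 to 3. For PDCD1 the ratio therefore decides nothing about B cells.

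Red-cell transcripts stood out in the M0 libraries of sets A and B of donors 1 and 2, with 513 to 2189 HBB counts against at most 86.7 in the other 14 M0 libraries. HBB stood at 0% of the M0 level in the M2 libraries of the same donors and sets. This argues against blood cells carried into both arms alike and still present in both at the end. Levels at the end cannot tell unequal carry-over from a later loss in M2. For the platelet gene PPBP there is no such argument, with up to 471 counts in those M2 libraries against a mean of 1609 in the 4 M0 libraries. Of ALAS2, GATA1 and ITGA2B, 3 of 3 had a mean in the 4 libraries above each of the other M0 libraries. Platelets and young red cells without a nucleus can carry such transcripts, so these genes cannot tell nucleated precursors from RNA without them. The mast cell and basophil genes HDC (mean 202, at most 33.0 in the others) and CPA3 (89.6, at most 7.49) were high there too. Precursor cells that persisted or expanded without the cytokines stay open, and no biological explanation was tested.

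The M2 minus M0 effect differed between the unsuffixed set and sets A and B of donors 1 to 3 for 1256 genes by edgeR and for 0 by limma. With all libraries thinned to 36.1 M reads, 3641 genes had an unadjusted p under 0.05 by limma against 3660 before, which argues against depth. A library batch that shifts each gene alike in M0 and M2 cancels in this effect, apart from low genes. The 25.2% of genes with an unadjusted p under 0.05 by limma (3660, against at most 382 in the other sign flips) argue against that form of batch. They are the pattern itself and decide nothing about a batch that acts unequally on M0 and M2, which stays open. Culture medium cannot be told apart from the set, since the labels assign no medium to libraries, and the median absolute M0 difference of 0.32 (log2) decides nothing. A biological difference between the sets remains untested.

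All 32 sign flips of the donors were run for counts of genes. For all genes 1 of 32 gave as many (6209, highest other 0), as for set A (1 of 32, 3857, highest other 0), set B (1 of 32, 4184, highest other 1) and ITIM receptors (1 of 32, 23, highest other 0). A share of 1 of 32 (0.031) is the smallest that these flips allow. It is under 0.05, which argues against chance without excluding it, and these counts share donors and are not separate tests. The ITIM receptors are part of the count of all genes, in which the other flips called 0. Their share was fixed by that count and adds nothing to it. For the number of gene lists nothing argues against chance, as 5 of 32 flips gave 16 or more (real 16, highest other 16). List by list, 12 of the 16 called lists had 1 of 32 flips as large and 4 had more. Lists that were not called also had 1 of 32, so this share does not set the called lists apart. These were the MHC class I, ITIM phosphatase, osteoclast-type, metallothionein, monocyte and platelet lists. For the difference between sets A and B 32 of 32 flips gave as many (real 0, highest other 0), an outcome that a real count of 0 fixes and that says nothing about chance. Set C (1680, highest other 0) and the unsuffixed set (3252, highest other 0) allow 4 flips each, in which 1 gave as many, the unsuffixed set against A and B 4 of 4 (0, highest other 0) and the donor groups 10 of 10 splits (0, highest other 0), too few for a share under 0.05.

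A donor lay far from the other 5 in 20 of 298 groups tested, where chance gives about 14.9. Values are the gap to the nearest donor as a share of the range. In M0, donor 3 was low for CCL18 (0.652) and SSTR2 (0.741) and high for PID1 (0.715) and FYN (0.653), and donor 6 low for CLEC10A (0.703) and SERPINB2 (0.732). Donor 2 was high for CYP24A1 (0.833) and donor 1 for MT1M (0.811), both at under 3 counts, donor 5 high for IFI27 (0.653) and donor 1 low for LILRB3 (0.699). In M2, donor 2 was low for FCGR3A (0.868), SSTR2 (0.652) and SIT1 (0.747) and high for SRC (0.714), and donor 5 low for IL17RB (0.657) and high for PDCD1 (0.667). Donor 1 was low for F5 (0.764) and high for LILRB2 (0.691), donor 3 low for SLC2A5 (0.733), and HBB was above 0 in donor 6 alone (1), at 0.288 counts.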

How the results depend on the processing

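Tests without sets A and B of some donors, with donors 4 to 6 only, of lists without the unsuffixed set, and with edgeR and DESeq2 for named genes or edgeR between sets, and of the vitamin D list without CYP27B1, were chosen after seeing the data. Counts of genes stayed within 1.5 times of 3207 higher and 3002 lower except as follows. Set A alone gave 1667 lower, set B alone 1816 lower, set C alone 981 higher and 699 lower, the unsuffixed set alone 1769 and 1483, donors 4 to 6 only 1997 lower, and a log2 fold change of at least 1 as well 1096 and 554. Single sets and 3 donors hold fewer samples. With no donor block, so without the pairing, 2321 genes were higher and 2053 lower, and ITIM receptors past the threshold went from 23 to 15, and to 10 in set C alone. Without the block 20 of 147 named genes and 5 lists lost their call. Against 16 lists called at the preset correlation, camera called 0 with an estimated correlation (5 of 35 unadjusted, 19 by fry) and 10 in the unsuffixed set alone at the preset one. Leaving out each donor gave 2720 to 3004 genes higher, 2335 to 2771 lower, 12 to 18 lists and 18 to 23 receptors. LILRB2, TREM2, INHBA, CDK1, PPBP, HBB, FCRL1 and CD33 lost their call without at least 1 donor.

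Signs turned, with the cause not tested, for TREM2 (-0.40 in the unsuffixed set alone and -0.10 without sets A and B of donors 1 to 3), HLA-DRA (-0.0033), CAMP (-1.19), LILRB3 (-0.51, past the threshold there and not over all libraries) and the median of the complement list (-0.045) in the unsuffixed set alone, the median of the proliferation list (-0.29) in set A alone, and PPBP (2.95 in the unsuffixed set alone, 0.40 without sets A and B of donors 1 and 2, 0.51 without those of donors 1 to 3). In set C alone CCR7 (0.10), FCRL5 (0.079) and CDK1 (-0.023) turned, and in TPM MT-ND6 (0.14). Over all settings the named genes gave 2582 values with an unchanged call, 189 that lost it, 1 that gained it and 12 that turned with a call at stake, and the lists 555, 61, 12 and 2. Among the values with an unchanged call 25 of genes and 49 of lists, which passed in neither setting, had the opposite sign. In TPM the inflammatory and dendritic cell lists lost their call and the MHC class II and ITIM lists gained one, and centring on the median ended the same 2 calls. The fit in TPM had its own filter of 0.5 TPM, so list members can differ there and its changes cannot be put down to the scale alone. No scaling moved the median of all genes by over 0.1. The count of genes in the authors' deposited table past the threshold here was 1531, and 1338 without the block.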

Other observations

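The predictions for both gene families below were written before their values were seen, and the split of the metal and oxidative stress genes and the test without CYP27B1 came after.

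The list of metallothionein and oxidative stress genes was not called as a whole (camera adjusted p = 0.493), and 4 of 21 members did not pass. The members past the threshold were sorted by family after their values were seen, and this split was not tested. The metallothioneins MT2A (1.97), MT1X (2.35), MT1F (2.49), MT1E (2.67), MT1M, MT1G and MT1H and the zinc transporters SLC39A8 (2.83) and SLC30A1 (0.62) rose, while genes of the oxidative stress response fell, among them SLC7A11 (-1.88), NQO1 (-1.82), OSGIN1 (-1.30), TXNRD1 (-0.87), GCLM (-0.64) and ME1 (-0.54). HMOX1, often counted with the latter, rose by 0.86. After centring on the median 10 members rose and 8 fell, and by edgeR 10 and 8. Reads of the near-identical MT1 genes cannot be assigned with certainty, so single members of that family are uncertain.

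CYP24A1 is a classic target of the vitamin D receptor, so one hypothesis was that other targets rose with it. Of 15 listed genes tested, 8 rose and 1 fell, including TMEM37 (1.69 ± 0.31) and CA2 (1.53 ± 0.14), and VDR itself did not pass (-0.012 ± 0.14). The median was 0.80 (bootstrap 95% interval -0.012 to 1.09, which includes 0) and the camera p was 0.00796, but 0.0779 with an estimated correlation. CYP27B1 (2.68 ± 0.32) lies upstream of the receptor, so its rise does not by itself show that receptor targets rose. Without it 7 of 14 rose and 1 fell, with a median of 0.54 (0.0085 to 1.09) and a camera p of 0.0194, or 0.0888 with an estimated correlation. The values are consistent with the hypothesis at the preset correlation only.

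CCL24, FCER2, CD200R1, CLEC10A and CD209, which IL-4 is known to induce, fell, so a second hypothesis was that other IL-4/STAT6 targets fell too. Dendritic cell markers, among them IRF4 (-3.69), fell as well (7 of 15, with 2 that rose), so a change in another cell type was not excluded. The data went the other way without excluding it: of 11 tested, 5 rose and 2 fell, with a median of 0.31 (bootstrap 95% interval -0.39 to 0.78; camera p = 0.133). MAOA (1.69 ± 0.17) and GATM (0.87 ± 0.12) rose, and SOCS1 (-0.87 ± 0.23) and CHST7 (-0.62 ± 0.10) fell.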
